A study of Andrographis paniculata with 12 samples.

How the data were processed

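Leaves of Andrographis paniculata, a medicinal herb of the Acanthaceae that makes diterpene lactones such as andrographolide, were sampled 0, 12, 24 and 48 h after the start of treatment with methyl jasmonate (MeJA), the volatile methyl ester of the plant hormone jasmonic acid. Per the labels, 3 biological replicates were taken at each of the 4 times, 12 samples in all, and poly(A)-enriched RNA was sequenced as strand-specific paired-end libraries on an Illumina HiSeq instrument. The series has no untreated leaves at 12, 24 or 48 h, so each later time was compared with the leaves taken at 0 h. The labels give no clock times. If all treatments began at 1 clock time, the samples at 0, 24 and 48 h share a time of day and those at 12 h do not.

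The data are 1 deposited table with 1 expression signal per assembled gene and time, in 4 columns, per the file headers. The authors had averaged the replicates before they deposited it: all of the values are whole multiples of 0.001 divided by 3, within a tolerance of 0.001 of that step, as a mean of 3 values with 3 decimals would be. The submitters' processing notes name CASAVA, FastQC 0.11.3, Trimmomatic 0.33 and RSEM 1.2.19 without giving their roles. The unit of the deposited signal (TPM, FPKM or a scaled form), the assembler, the aligner and the reference are not given in the sources used here. The columns sum to 866243, 973347, 965390 and 932776 at 0, 12, 24 and 48 h, so the deposited rows have no common total. Whether the values were set to 1 total over a larger set of genes is not known. They hold no read counts, and the depth behind a value is unknown. An assembled gene stands for 1 cluster of assembled transcripts, and a gene of the plant can be split over several of them or merged with its copies. Names are those of the best Swiss-Prot hit the authors' table gives (or, where it gives none, of the TrEMBL hit), so they state similarity and not identity. Of 32064 assembled genes, 20219 had a Swiss-Prot name, 5133 a TrEMBL name alone and 6712 none. Another row was emptied before it was used here. Gene coordinates are not reported, since the table gives none, and the table's names could not be joined to a reference.

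Because the table has 1 mean per time, no spread between replicates can be computed. The tests planned before the data were examined (a negative binomial model on counts or limma on log values per library, and camera for gene lists) could not be run, and no p-value, SD or replicate number stands behind any value. A rule of size took the place of the test, chosen after the unit was seen: a gene is counted as higher or lower where log2(level + 1) differs by 1 or more, which is 2-fold, among the 29399 genes with a level of at least 1 at 1 or more times. Differences are on the log2(level + 1) scale, which understates those of genes at low levels. The counts describe these means and do not say how many differences exceed the variation between plants.

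The 45 gene lists (pathways, hormone genes, transcription factor families, and markers of other tissues) were fixed by name patterns before the data were examined. The median log2 difference of each list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list is called higher or lower where its median lies outside percentiles 2.5 to 97.5 and the list has at least 5 members. A percentile describes these columns and is not a p-value, and genes of 1 list are not independent. A list can be called lower while it has members on both sides, since the random lists have a median of their own.

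The named genes follow a rule also fixed beforehand. For each comparison with 0 h it takes the 5 annotated genes with the largest positive and the 5 with the largest negative log2 difference among those with a mean level of at least 10, the 2 most different members of 13 main lists, the most different member of each other called list, and up to 6 diterpene synthases. For 24 h against 12 h and for 48 h against 24 h it takes 3 genes each way. The difference in size stood in for the p-value of the planned rule, and its demand that libraries do not overlap could not be applied. In addition, 30 annotated genes and 1 without a database hit were named after their values were seen, each marked so in the text by the words "chosen afterwards".

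The steps were tested on simulated data for 12 h against 0 h on 29399 genes, with noise of SD 0.2 on the log2 scale and 50 genes planted at each fold. The size rule found 50 of 50 genes at 4-fold, 50 of 50 at 8-fold, 48 of 50 at 3-fold and 5 of 50 at 1.5-fold. It counted 1 of 29149 unchanged genes. The noise was assumed. In a further simulation of unchanged leaves with SD 0.5, on average 1200 of 29399 genes were counted as higher and 1199 as lower. The planted genes, and those of the shifted list, had a level of at least 10 at 0 h. A list of 50 genes shifted by 0.5 was placed at percentile 100, and 8 of 200 random lists of 30 genes lay outside the bounds. Alternatives tried were a pseudocount of 0.1 and no filter on low values, both planned, and, added after the data were seen, a level of at least 10, a 4-fold rule, median-of-ratios scaling of the 4 columns, leaving out the 10 genes with the highest mean level, summing assembled genes of 1 component that share a Swiss-Prot entry, and keeping 1 assembled gene per entry in the lists. Assembled genes of 1 component with the same protein name are called pieces below, though they may be pieces or copies of 1 gene. Summing joined only those that share a whole Swiss-Prot entry, species included, so pieces with entries of different species stayed apart. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.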

Results

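Leaf RNA of Andrographis paniculata was profiled at 0, 12, 24 and 48 h of methyl jasmonate (MeJA) treatment, with 3 biological replicates labelled at each of the 4 times. The table used here gives 1 mean level per assembled gene and time, in the authors' normalised units, so every level below is the authors' mean and none has an error or a replicate number. The values hold no read counts and the depth behind them is unknown. Of 32064 assembled genes, 29399 had a level of at least 1 at 1 or more times. The number of genes listed at 0 was 1115 at 0 h, 1109 at 12 h, 1280 at 24 h and 1393 at 48 h. At 0 h the gene with the highest level encoded a Rubisco small chain (TR76467|c8_g3, chosen afterwards), at 19739 or 2.28% of the column sum. At the 3 later times it was an assembled gene with no database hit (TR44405|c11_g2, chosen afterwards), at 17306, 95796, 77773 and 53574 over the time course. The 10 genes with the highest mean level made up 9.26%, 19.95%, 18.8% and 22.5% of the column sums at 0, 12, 24 and 48 h.

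The comparison of 12 h with 0 h asks which leaf transcripts differ early in the MeJA treatment. The lists of jasmonate biosynthesis and signalling and of early steps of terpenoid synthesis were higher at 12 h, and those of photosynthesis, chlorophyll synthesis, auxin response and the cell wall were lower. Of the 29399 genes, 4413 were higher and 5214 lower by 2-fold or more, together 9627 genes or 32.7%. Among the 43 lists with at least 5 members, 15 lay above and 10 below the random lists matched on level.

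**Figure D1:**
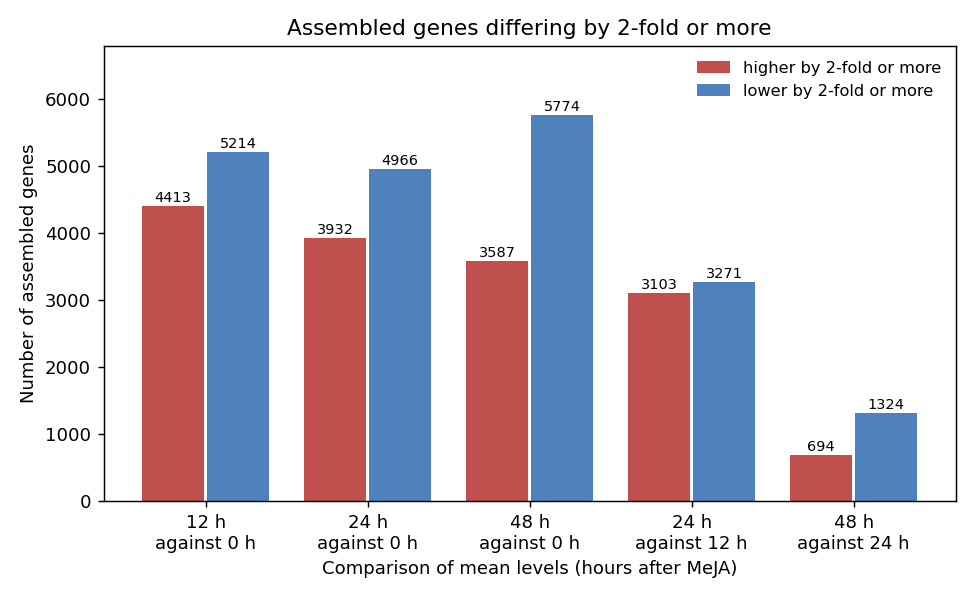
Number of assembled genes (vertical axis) whose mean level was higher (red bars) or lower (blue bars) by 2-fold or more in each of 5 comparisons of times (horizontal axis). The count was largest for 12 h against 0 h, with 4413 higher and 5214 lower (with a pseudocount of 0.1 it was 12646 at 12 h and 12703 at 48 h), and smallest for 48 h against 24 h, with 694 and 1324.

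Jasmonate signalling had the highest median of the 43 lists at 12 h. Of its 40 genes, 25 were higher and 2 lower, with a median log2 difference of 2.19. Within this list the 22 genes named TIFY, the family of JAZ repressors that jasmonate removes from MYC factors, had a median of 3.46 and 19 of them were higher. TIFY 9 (TR81360|c4_g2) was at 0.977 at 0 h and 836 at 12 h, and TIFY 5A (TR24440|c0_g2) at 0.933 and 359.8. The transcription factor MYC2 (TR24422|c0_g1, chosen afterwards) was at 14.1 and 178. The 3 hits to the jasmonate receptor subunit COI1 had a median of -0.75 and 1 of them was lower by 2-fold. Of 41 jasmonate biosynthesis genes, 21 were higher and 4 lower, with a median of 1.10. Allene oxide cyclase 2 (TR76470|c1_g4), which forms the ring of the jasmonate precursor, was at 4.95 at 0 h and 945 at 12 h. Jasmonate O-methyltransferase (TR50123|c1_g2), which makes MeJA from jasmonic acid, was at 0.0457 and 47.9. All 5 genes named 13-lipoxygenase, the entry step to jasmonates, were higher, as was 1 of the 9 named 9-lipoxygenase, of which 3 were lower. The 13-lipoxygenase TR60361|c4_g4 (chosen afterwards) was at 178 at 0 h and 5078 at 12 h. Of 19 jasmonate catabolism genes, 10 were higher and none lower, among them a cytochrome P450 of the CYP94 family (TR35519|c0_g1, 0.470 at 0 h and 376 at 12 h), a family known to oxidise jasmonoyl-isoleucine.

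Terpenoid genes were partly higher at 12 h. The methylerythritol phosphate (MEP) pathway, the plastid route to the isoprenoid units of diterpenes, had 11 of 24 genes higher and 2 lower, with a median of 0.80. Its 2 most different members were CDP-methylerythritol kinase (TR14286|c0_g2), at 19.8 at 0 h and 227 at 12 h, and the reductoisomerase DXR (TR50722|c0_g4), at 40.3 and 407. Hydroxymethylbutenyl diphosphate reductase (TR51094|c2_g1, chosen afterwards), the last enzyme of the pathway, was at 327 and 1327. In the mevalonate list, the cytosolic route, 9 of 17 genes were higher and none lower, with a median of 1.02. A gene named HMG-CoA reductase (TR59188|c3_g3), the main control step of that route, was at 6.41 and 198. The 6 genes of that name had a median of 1.38, with 4 higher and none lower. The list also holds hydroxymethylglutaryl-CoA lyase (TR79263|c1_g1), an enzyme of leucine breakdown, at 8.32 and 66.9. Of 18 prenyl diphosphate synthase genes, 7 were higher and 3 lower, with a median of 0.94. The small subunit of geranylgeranyl diphosphate synthase (TR65835|c2_g2) was at 73.2 and 702, a farnesyl diphosphate synthase (TR40024|c0_g1) at 0.407 and 21.1, and geranylgeranyl diphosphate synthase (TR18674|c2_g3, chosen afterwards) at 100.4 and 868. The 5 diterpene synthases were all hits to ent-copalyl diphosphate synthase, the enzyme that starts labdane-type cyclisation, and lay on 2 assembly components. At 12 h, 3 of them were higher and 2 lower, and their median of 1.02 lay inside the random lists at percentile 96.6. The most abundant, TR66725|c19_g3, was at 359 and 834, its neighbours TR66725|c19_g4 and TR66725|c19_g1 were at 11.2 and 25.4 and at 1.43 and 3.91 (the last not counted with median-of-ratios scaling, at 0.94 on the log2(level + 1) scale), and the remaining TR57874|c0_g2 and TR57874|c0_g3 were at 1.84 and 0.108 and at 2.09 and 0.221. Among 15 squalene and triterpene genes 4 were higher and 4 lower, and 2 squalene monooxygenase hits, TR74157|c6_g11 and TR32008|c0_g1, were at 40.2 and 4.30 and at 19.2 and 0.646. The gibberellin list had 5 of 14 genes higher and 3 lower, with a median of 0.65, and its most different member was a gibberellin 2-oxidase (TR33497|c0_g1), an enzyme that inactivates the hormone, at 0.894 and 475.007.

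Some protease inhibitor hits were among the genes with the largest positive differences at 12 h. Of 35 anti-herbivore genes, 11 were higher and 2 lower, with a median of 0.58. At all 3 times this list includes 9 hits to purple acid phosphatases, which had a median of 0.39 at 12 h with 1 higher. A trypsin inhibitor (TR34236|c2_g2) was at 17.0 at 0 h and 7234 at 12 h, and a glutamyl endopeptidase inhibitor (TR52219|c0_g1) at 0.572 and 536. The Kunitz-type factor Xa inhibitor hit TR83819|c4_g1 was at 16.3 and 11976, and the hits to sporamin A, a storage protein of the same fold, were at 6.76 and 11365 (TR45313|c4_g1) and at 0.00300 and 1054 (TR45313|c4_g2). The other 2 of the 5 largest positive differences were a fatty acyl-CoA reductase (TR80732|c10_g3), at 2.28 and 2321, and an isoleucine N-monooxygenase of the CYP79 type (TR74526|c7_g2), at 0.466 and 952.

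Phenylpropanoid and lignin genes had 24 of 74 members higher and 11 lower, with a median of 0.61. Of the 74, 17 were hits to caffeoylshikimate esterase. Caffeoylshikimate esterase (TR45843|c1_g2) was at 1.01 and 329, and a 4-coumarate-CoA ligase (TR32294|c0_g2) at 0.325 and 17.0. Flavonoid genes had 23 of 106 members higher and 25 lower, and their median of -0.24 lay below the random lists at percentile 0.31. The commonest Swiss-Prot entry name among them was HIDM, with 18 of the 106 members. An isoflavone reductase-like gene (TR13440|c4_g3) was at 6.66 and 1424, and a flavonoid 3',5'-hydroxylase (TR26978|c11_g7) at 95.4 and 0.554. In the list of leaf senescence and chlorophyll breakdown, 14 of 23 genes were higher and 6 lower, with a median of 1.92. In that list 13 members were hits to pheophytinase, and STAY-GREEN (TR74648|c2_g2), which removes magnesium from chlorophyll, was at 0.0873 and 189.6. The ethylene list had 55 of 159 genes higher and 30 lower, with a median of 0.40. Its most different member, an ethylene receptor 1 hit (TR79615|c17_g1) on the assembly component of a cytochrome P450 hit, was at 19.1 and 4659.9. Transcription factor lists above the random lists were NAC, with 18 of 59 genes higher and 7 lower, AP2/ERF, with 39 of 117 higher and 21 lower, and bHLH, with 27 of 102 higher and 22 lower. Their most different members were NAC72 (TR83229|c0_g1), at 3.95 and 308, ERF3 (TR15703|c0_g1), at 0.0720 and 35.2, and bHLH19 (TR49758|c6_g1), at 8.22 and 386. The phloem and xylem markers had 4 of 19 genes higher and 3 lower, and the sugar exporter SWEET14 (TR31741|c1_g8) was at 0.0387 and 5.47.

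Light reaction genes had the lowest median of the 43 lists at 12 h. Of the 90 genes, 64 were lower and 1 higher, with a median of -2.56. The 28 genes named chlorophyll a-b binding protein had a median of -4.89 and 26 of them were lower. A light-harvesting protein of photosystem II type III (TR32853|c2_g2) was at 1944 at 0 h and 2.45 at 12 h, and a chlorophyll a-b binding protein 13 (TR20636|c0_g2) at 2020.06 and 3.08. Of 20 Calvin cycle genes, 12 were lower and none higher, with a median of -1.81. Rubisco activase (TR86921|c9_g1), which reopens the active site of Rubisco, was at 7713 and 31.0. Of 20 chlorophyll biosynthesis genes, 12 were lower and 1 higher, and the magnesium-chelatase subunit ChlH (TR67008|c0_g2) was at 328 and 4.25. The circadian clock list had 11 of 45 genes higher and 13 lower, with a median of -0.32. The morning gene LHY (TR49676|c1_g3) was at 383 and 0.700, and REVEILLE 8 (TR50358|c1_g4) at 93.4 and 0.357, while the evening gene GIGANTEA (TR32264|c0_g2, chosen afterwards) was at 25.0 and 212.

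The auxin, cell wall, MYB, defence and stomata lists were also lower at 12 h. Of 141 auxin genes, 79 were lower and 16 higher, with a median of -1.27. The small auxin-induced proteins 10A5 (TR38487|c0_g1) and ARG7 (TR41518|c0_g1) were at 334 and 336 at 0 h and listed at 0 at 12 h, and the auxin-binding protein ABP19a (TR86742|c0_g1) was at 2681 and 9.38. Of 225 cell wall genes, 90 were lower and 23 higher, and a xyloglucan endotransglucosylase (TR73237|c0_g1), which loosens and rejoins wall polymers, was at 45.8 and 0.0487. The MYB list had 43 of 132 genes lower and 23 higher, although its most different member, a MYB306-like gene (TR38537|c0_g2), was at 1.67 and 121. Of 124 defence protein genes, 37 were lower and 23 higher, with a median of -0.32. Of these, the 18 lipid transfer proteins had a median of -1.79 with 11 lower, and the other 106 genes one of -0.14 with 26 lower and 20 higher. The pathogenesis-related protein PR-1 (TR36497|c0_g1), a marker of salicylic acid responses, was at 56.9 and 0.0373, and a pEARLI1-like lipid transfer protein (TR73207|c14_g18) at 1243 and 33.3. Stomata markers had 18 of 37 genes lower and 4 higher. In that list 17 genes were hits to a guard cell aspartic protease, of which 12 were lower, and EPIDERMAL PATTERNING FACTOR-like 9 (TR26482|c0_g5), which promotes stomata, was at 75.1 and 1.09.

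The other 18 lists lay inside the random lists at 12 h in the main setting. These were diterpene synthases, other terpene synthases, squalene and triterpene enzymes, cytochrome P450, UDP-glycosyltransferases, 2-oxoglutarate-dependent dioxygenases, carotenoid biosynthesis, peroxidases and glutathione transferases, abscisic acid, salicylic acid, WRKY factors, heat shock proteins, cytosolic ribosomal proteins, cell cycle and histones, starch and sugar, and epidermis, flower and root markers. If all leaves were treated at 1 clock time, those taken at 12 h differ from those at 0 h in time of day as well as in treatment, and no untreated leaves of 12 h were analysed here. Calls that depended on the counting of copies or on a filter at 12 h were those of the MEP pathway, gibberellin, flavonoid, clock, defence, MYB, NAC, bHLH, AP2/ERF and vascular lists. With 1 assembled gene per Swiss-Prot entry the MEP median was 1.03 at percentile 96.9 and the defence median lay at percentile 25.1, and with a level of at least 10 the clock median was 0.11 at percentile 56.4. With a level of at least 10, other terpene synthases were above the random lists (median 3.38 in place of 0.13) and the carotenoid (-0.59) and flower (-0.69) lists below, while flower markers were above with 1 assembled gene per entry (0.45), epidermis markers below with pieces summed (-0.63) and UDP-glycosyltransferases below in 4 settings.

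The jasmonate, MEP and phenylpropanoid lists were higher in the comparison of 24 h with 0 h. Photosynthesis, auxin and cell wall genes were lower, and cytosolic ribosomal protein genes, inside the random lists at 12 h, were also lower. By 2-fold or more, 3932 genes were higher and 4966 lower, together 8898 or 30.3%. With a level of at least 10 the numbers were 2434 and 2404, or 50.3% higher in place of 44.2%. Here 16 lists lay above and 10 below the random lists.

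The ent-copalyl diphosphate synthase TR66725|c19_g3 was at 3374 at 24 h against 359 at 0 h. The other 2 members of its component were at 116 (TR66725|c19_g4) and 24.7 (TR66725|c19_g1), while TR57874|c0_g2 and TR57874|c0_g3 were at 0.0557 and 0.448. The diterpene synthase median was 3.23, with 3 genes higher, all of 1 component, and 2 lower. With a level of at least 10, with pieces summed or with 1 assembled gene per Swiss-Prot entry, the list had under 5 members and no call at 24 h or 48 h. Of 24 MEP genes, 12 were higher and 1 lower, with a median of 1.06. CDP-methylerythritol kinase was at 212, and deoxyxylulose phosphate synthase 2 (TR67055|c4_g1), the entry enzyme of the pathway, was at 1135 against 185 at 0 h. The HMG-CoA reductase TR59188|c3_g3 was at 63.6 and the lyase at 54.9. The mevalonate list had 6 of 17 genes higher and none lower, with a median of 0.48 inside the random lists. The list was above them with a pseudocount of 0.1 (0.73), a level of at least 10 (1.01) and 1 assembled gene per Swiss-Prot entry (0.87). The prenyl diphosphate synthases, 7 of 18 higher and 4 lower, also lay inside them at percentile 80.3, and above them with a level of at least 10 (0.88). A small subunit of geranylgeranyl diphosphate synthase (TR65835|c2_g1) was at 13.6 against 0.763, and the farnesyl diphosphate synthase at 14.9. The more abundant piece of that subunit, TR65835|c2_g2, was at 572 against 73.2, and the geranylgeranyl diphosphate synthase TR18674|c2_g3 at 274 against 100.4. Other terpene synthases had 7 of 10 genes higher and none lower, with a median of 1.60, and a germacrene A synthase hit (TR23775|c1_g2), a sesquiterpene enzyme, was at 204 against 0.0910. Among the 15 squalene and triterpene genes, inside the random lists with 1 higher and 4 lower, lupeol synthase (TR57922|c0_g1) was at 122 against 18.9, and the squalene monooxygenase TR32008|c0_g1 at 0.508. The cytochrome P450 list had 55 of 185 genes higher and 43 lower, with a median of 0.26, and its most different member was the CYP94 gene at 233.

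**Figure D2:**
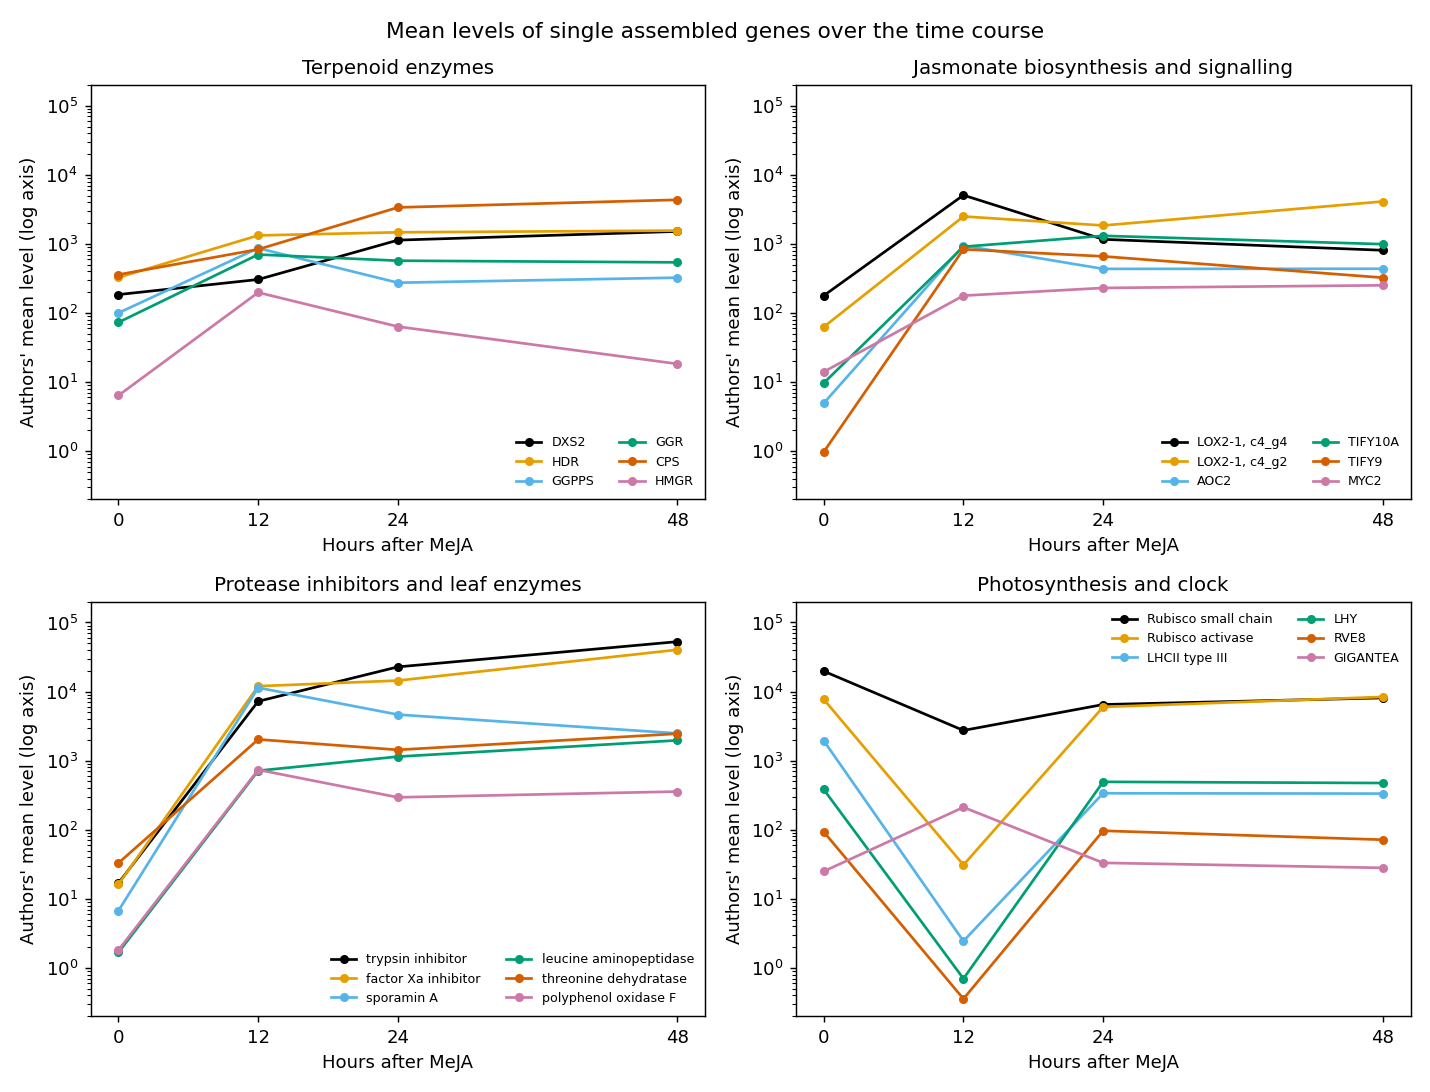
Authors' mean level (vertical axis, log scale, no unit given) of 24 assembled genes against hours after MeJA (horizontal axis), in 4 panels by function, with 1 line per gene and no error bars because the table holds means alone. The ent-copalyl diphosphate synthase (CPS) line goes from 359 at 0 h to 4348 at 48 h, and the LHY line is at 0.700 at 12 h and between 383 and 494 at the other times.

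Jasmonate signalling genes were higher in 26 of 40 cases and lower in 2 at 24 h, with a median of 2.34, and TIFY 10A (TR47119|c4_g4) was at 1311 against 9.70 and TIFY 9 at 661. Jasmonate biosynthesis genes were higher in 17 of 41 cases and lower in 7, with a median of 0.68. Allene oxide cyclase 2 was at 435, and the 13-lipoxygenase TR60361|c4_g2 at 1849 against 62.8, after 2498 at 12 h. The 13-lipoxygenase TR60361|c4_g4, a piece of the same component and entry, was at 1165 after 5078 at 12 h. Jasmonate catabolism genes were higher in 8 of 19 cases and lower in 1. Anti-herbivore genes were higher in 16 of 35 cases and lower in 1. The trypsin inhibitor was at 22771, the factor Xa inhibitor at 14436, the sporamin TR45313|c4_g1 at 4643 and the glutamyl endopeptidase inhibitor at 504.2. Leucine aminopeptidase (TR50768|c4_g1), known as a wound-response protein in the nightshade family, was at 1145 against 1.68, and a benzoate carboxyl methyltransferase hit (TR13462|c1_g1) at 1703 against 2.38. Phenylpropanoid genes were higher in 34 of 74 cases and lower in 6, with phenylalanine ammonia-lyase (TR19096|c0_g3) at 59.4 against 2.64 and caffeoylshikimate esterase at 54.9. Flavonoid genes were higher in 25 of 106 cases and lower in 21, inside the random lists. In that list the isoflavone reductase-like TR13440|c4_g3 was at 2739, and a flavonoid 3',5'-hydroxylase (TR26978|c11_g1) was at 230.3 at 0 h and listed at 0 at 24 and 48 h, while TR26978|c11_g7 was at 41.8 and 84.8 at these times.

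Senescence genes were higher in 13 of 23 cases and lower in 1 at 24 h, and a pheophytinase hit (TR66725|c16_g2) was at 115 against 0.692. Ethylene genes were higher in 51 of 159 cases and lower in 24, with the ethylene receptor hit at 3982. Also above the random lists were NAC factors, with 21 of 59 genes higher and 5 lower and a NAC72 hit (TR45774|c0_g1) at 113 against 0.187, and WRKY factors, with 14 of 83 higher and 5 lower and WRKY33 (TR80750|c1_g1) at 64.6 against 2.39. Peroxidases and glutathione transferases were higher in 20 of 81 cases and lower in 10, with a glutathione transferase (TR74651|c8_g1) at 272 against 18.6. Heat shock proteins were higher in 45 of 213 cases and lower in 19, although the most different member, a DnaJ homolog (TR74498|c2_g1), was at 20.1 at 0 h and listed at 0 at 24 h. With the pieces of its component summed, that difference was 0.34 in the positive direction. The phloem and xylem markers were higher in 3 of 19 cases and lower in 1, and SWEET14 was at 17.5.

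Light reaction genes were lower in 70 of 90 cases and higher in none at 24 h, with a median of -1.87. Photosystem II 5 kDa protein (TR53544|c0_g1) was at 109.6 against 1566, and a chlorophyll a-b binding protein (TR38081|c0_g1) was at 12.3 at 0 h and listed at 0. Calvin cycle genes were lower in 5 of 20 cases and higher in none, with a median of -0.61. Rubisco activase was at 5987 at 24 h against 7713 at 0 h, and a Rubisco small chain hit (TR53724|c0_g1) was at 10.54 at 0 h and listed at 0. Chlorophyll biosynthesis genes were lower in 10 of 20 cases, and the magnesium-chelatase subunit ChlI (TR83726|c0_g2) was at 0.238 against 48.5. Cytosolic ribosomal protein genes were lower in 96 of 299 cases and higher in 6, with a median of -0.79, although their most different member, a 60S L23a hit (TR75420|c0_g1), was at 14.7 against 1.31. Auxin genes were lower in 67 of 141 cases, with the auxin-induced protein 15A (TR17401|c0_g1) at 0.526 against 105. Cell wall genes were lower in 122 of 225 cases and higher in 15, with a xyloglucan endotransglucosylase (TR46569|c0_g2) at 1.01 against 124. Defence genes were lower in 43 of 124 cases and higher in 17. PR-1 was at 0.189, while an acidic chitinase (TR14062|c1_g1) was at 51.9 against 0.0313. MYB genes were lower in 33 of 132 cases and higher in 28, and MYB5 (TR79485|c1_g2) was at 252 against 1.78. Stomata markers were lower in 20 of 37 cases, although EPIDERMAL PATTERNING FACTOR 2 (TR26411|c3_g3), which restricts stomata, was at 61.7 against 0.175. Epidermis and cuticle markers were lower in 22 of 54 cases and higher in 12, with a ketoacyl-CoA synthase (TR58825|c0_g1) at 1.23 against 68.3. The 5 largest negative differences at 24 h were the flavonoid 3',5'-hydroxylase above, 2 pieces of the plastid protease FTSH 2 (TR32368|c2_g7 at 246 and TR32368|c2_g3 at 85.3 at 0 h, both listed at 0 at 24 h), a galactinol synthase (TR71349|c2_g3, 212 and 0.213) and a GDSL lipase (TR13865|c0_g5, 445 and 4.42). Another FTSH 2 piece of the same component (TR32368|c2_g5, chosen afterwards) was at 218.4 at 0 h and 291 at 24 h. Its entry is of another species, so summing did not join it to the 2 listed at 0. The flavonoid 3',5'-hydroxylase piece TR26978|c11_g7, at 95.4 at 0 h and 41.8 at 24 h, was likewise not joined to TR26978|c11_g1. With its pieces summed the galactinol synthase was lower by less than 2-fold, at -0.85 at 24 h and -0.30 at 48 h.

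The clock list was inside the random lists at 24 h, with 4 of 45 genes higher and 2 lower and a median of 0.19. LHY was at 494 and GIGANTEA at 33.2, against 383 and 25.0 at 0 h. Its 2 most different members were REVEILLE 3 (TR73858|c0_g2), at 12.7 against 1.61, and ELF4-LIKE 3 (TR42874|c0_g2), at 1.43 against 8.62. Also inside were the gibberellin, UDP-glycosyltransferase, 2-oxoglutarate-dependent dioxygenase, carotenoid, abscisic acid, salicylic acid, bHLH, AP2/ERF, cell cycle, starch, flower and root lists. The calls of the NAC, defence, MYB, epidermis and peroxidase lists were lost with 1 assembled gene per Swiss-Prot entry, with medians of 0.51, 0.11, 0.19, 0.38 and 0.21. The jasmonate biosynthesis call was lost with pieces summed, at a median of 0.41 and percentile 97.1, and that of the vascular markers with a level of at least 10, at percentile 93.4. Lists above the random lists in other settings alone were gibberellin (0.84 with a pseudocount of 0.1), bHLH (0.52 with a level of at least 10), starch (0.62 with a level of at least 10) and AP2/ERF (0.33 with 1 assembled gene per entry).

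In the comparison of 48 h with 0 h, a trypsin inhibitor, a factor Xa inhibitor hit and the most abundant copalyl diphosphate synthase had their highest levels of the 4 times. Ribosomal protein genes were lower in 155 of 299 cases, against 96 at 24 h, and cell wall genes in 133 of 225, against 122. By 2-fold or more, 3587 genes were higher and 5774 lower, together 9361 or 31.8%. Higher genes made up 38.3% of these, against 42.2% with median-of-ratios scaling and 43.1% with the 10 highest genes left out. Over all genes the median difference was 0.01 at 24 h and -0.09 at 48 h. The counts of ribosomal and cell wall genes at these 2 times are not corrected for this. Here 17 lists lay above and 10 below the random lists.

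The 5 largest positive differences at 48 h were the trypsin inhibitor at 52772, the factor Xa inhibitor at 40279, leucine aminopeptidase at 1967, benzoate carboxyl methyltransferase at 1319.5 and tryptophan synthase beta chain 2 (TR21161|c85_g3), at 542 against 0.672. The 5 hits to trypsin inhibitor BvTI, factor Xa inhibitor and sporamin, a group chosen afterwards around genes already named for their large differences, together made up 0.0115% of the column sum at 0 h, 3.27% at 12 h, 4.38% at 24 h and 10.3% at 48 h. Anti-herbivore genes were higher in 15 of 35 cases and lower in 3, and the glutamyl endopeptidase inhibitor was at 242. The copalyl diphosphate synthase TR66725|c19_g3 was at 4348, TR66725|c19_g4 at 79.9 and TR66725|c19_g1 at 24.6, while TR57874|c0_g3 was at 0.127 and TR57874|c0_g2 was listed at 0. The diterpene synthase median was 2.73, again with 3 genes higher and 2 lower. MEP genes were higher in 12 of 24 cases and lower in 2, with hydroxymethylbutenyl diphosphate synthase (TR59165|c5_g1) at 1178 against 138 and CDP-methylerythritol kinase at 201. Mevalonate genes were higher in 6 of 17 cases and lower in none, with a median of 0.83, the HMG-CoA reductase TR59188|c3_g3 at 18.4 and the lyase at 40.1. The 6 genes named HMG-CoA reductase had medians of 0.25 at 24 h and 1.06 at 48 h, with 2 and 4 higher and none lower. Prenyl diphosphate synthases were higher in 8 of 18 cases and lower in 5, and their median of 0.43 lay inside the random lists at percentile 97.4. They were above them with a pseudocount of 0.1 (median 0.74), a level of at least 10 (0.80), median-of-ratios scaling (0.52), the 10 highest genes left out (0.53) and 1 assembled gene per Swiss-Prot entry (1.68). The geranylgeranyl diphosphate synthase subunit TR65835|c2_g2 was at 541, and another geranylgeranyl diphosphate synthase hit (TR18674|c2_g1) was at 6.29 at 0 h and listed at 0. The more abundant piece of that component, TR18674|c2_g3, was at 325 against 100.4 at 0 h. Other terpene synthases were higher in 7 of 10 cases, with the germacrene A synthase hit at 227. Cytochrome P450 genes were higher in 57 of 185 cases and lower in 38, with a CYP71D hit (TR82346|c6_g1) at 140.2 against 0.156. Squalene synthase (TR16397|c0_g1) was at 0.0473 against 4.12, and the squalene monooxygenase TR32008|c0_g1 at 0.728. The gibberellin list was higher in 6 of 14 cases and lower in 3, with the gibberellin 2-oxidase at 147.

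Jasmonate signalling genes were higher in 26 of 40 cases and lower in 1 at 48 h, with a median of 2.02, TIFY 9 at 325 and TIFY 10A at 992. Jasmonate biosynthesis genes were higher in 16 of 41 cases and lower in 6, with a median of 0.57, the 13-lipoxygenase TR60361|c4_g2 at 4109.5 and allene oxide cyclase 2 at 437. The other 13-lipoxygenase piece of that component, TR60361|c4_g4, was at 809, below its 5078 at 12 h. Jasmonate catabolism genes were higher in 10 of 19 cases and lower in 1, with the CYP94 gene at 114. Phenylpropanoid genes were higher in 31 of 74 cases and lower in 5, with caffeoylshikimate esterase at 51.4, while a cinnamate 4-hydroxylase (TR70016|c0_g5) was at 8.10 against 244. Flavonoid genes were higher in 31 of 106 cases and lower in 22, inside the random lists, with the isoflavone reductase-like gene at 1928. Senescence genes were higher in 15 of 23 cases and lower in 3, with STAY-GREEN (TR28938|c0_g1) at 293 against 1.88. Ethylene genes were higher in 43 of 159 cases and lower in 33, with the receptor hit at 4786. NAC genes were higher in 17 of 59 cases and lower in 7, with TR45774|c0_g1 at 68.6, and WRKY genes in 14 of 83 cases and lower in 11, with WRKY33 at 53.5. Heat shock genes were higher in 36 of 213 cases and lower in 27, with the DnaJ homolog again listed at 0 and, with pieces summed, at a difference of 0.36. Starch and sugar genes were higher in 19 of 79 cases and lower in 11, and the most different member was an amylase and subtilisin inhibitor hit (TR83819|c4_g2), a protein that acts on enzymes and not a starch enzyme, at 2219 against 15.4.

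Light reaction genes were lower in 69 of 90 cases and higher in none at 48 h, with a median of -1.99. Photosystem II 5 kDa protein was at 93.0 and the photosystem II repair protein PSB27 (TR50109|c0_g1) at 38.9 against 590.3. Calvin cycle genes were lower in 6 of 20 cases, with a median of -0.64. A Rubisco large chain hit (TR37434|c0_g1) was at 11.6 against 47.5, the Rubisco small chain TR76467|c8_g3 was at 8099 against 19739, and Rubisco activase was at 8364. Chlorophyll biosynthesis genes were lower in 10 of 20 cases, and ChlI was listed at 0. Ribosomal protein genes were lower in 155 of 299 cases and higher in 4, with a median of -1.04 and a 60S L5 hit (TR59191|c1_g1) at 2.26 against 29.1. Cell wall genes were lower in 133 of 225 cases and higher in 14, with a xyloglucan endotransglucosylase (TR32216|c0_g2) at 1.14 against 318. Auxin genes were lower in 82 of 141 cases and higher in 8, with auxin-induced protein 15A (TR81280|c1_g3) at 4.03 against 658. Defence genes were lower in 54 of 124 cases and higher in 17, with 2 pEARLI1-like lipid transfer proteins at 8.34 against 1243 (TR73207|c14_g18) and 8.25 against 1173 (TR73207|c14_g9). MYB genes were lower in 40 of 132 cases and higher in 21, although MYB5 was at 318. Stomata markers were lower in 20 of 37 cases and higher in 2, with EPIDERMAL PATTERNING FACTOR 2 at 63.1, and epidermis markers in 20 of 54 cases and higher in 13, with the ketoacyl-CoA synthase at 0.880. The 5 largest negative differences at 48 h were the FTSH 2 piece TR32368|c2_g7 and the flavonoid 3',5'-hydroxylase TR26978|c11_g1, both listed at 0, the gibberellin-responsive GAST1 (TR73025|c0_g2) at 0.678 against 349, the xyloglucan endotransglucosylase and the galactinol synthase at 0.491. The FTSH 2 piece TR32368|c2_g5, not joined by summing, was at 419 against 218.4 at 0 h. The clock list was inside the random lists with a median of -0.04, ELF4-LIKE 3 (TR42874|c0_g1) at 2.02 against 21.8 and the pseudo-response regulator APRR5 (TR63929|c5_g2) at 16.2 against 3.05.

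**Figure D3:**
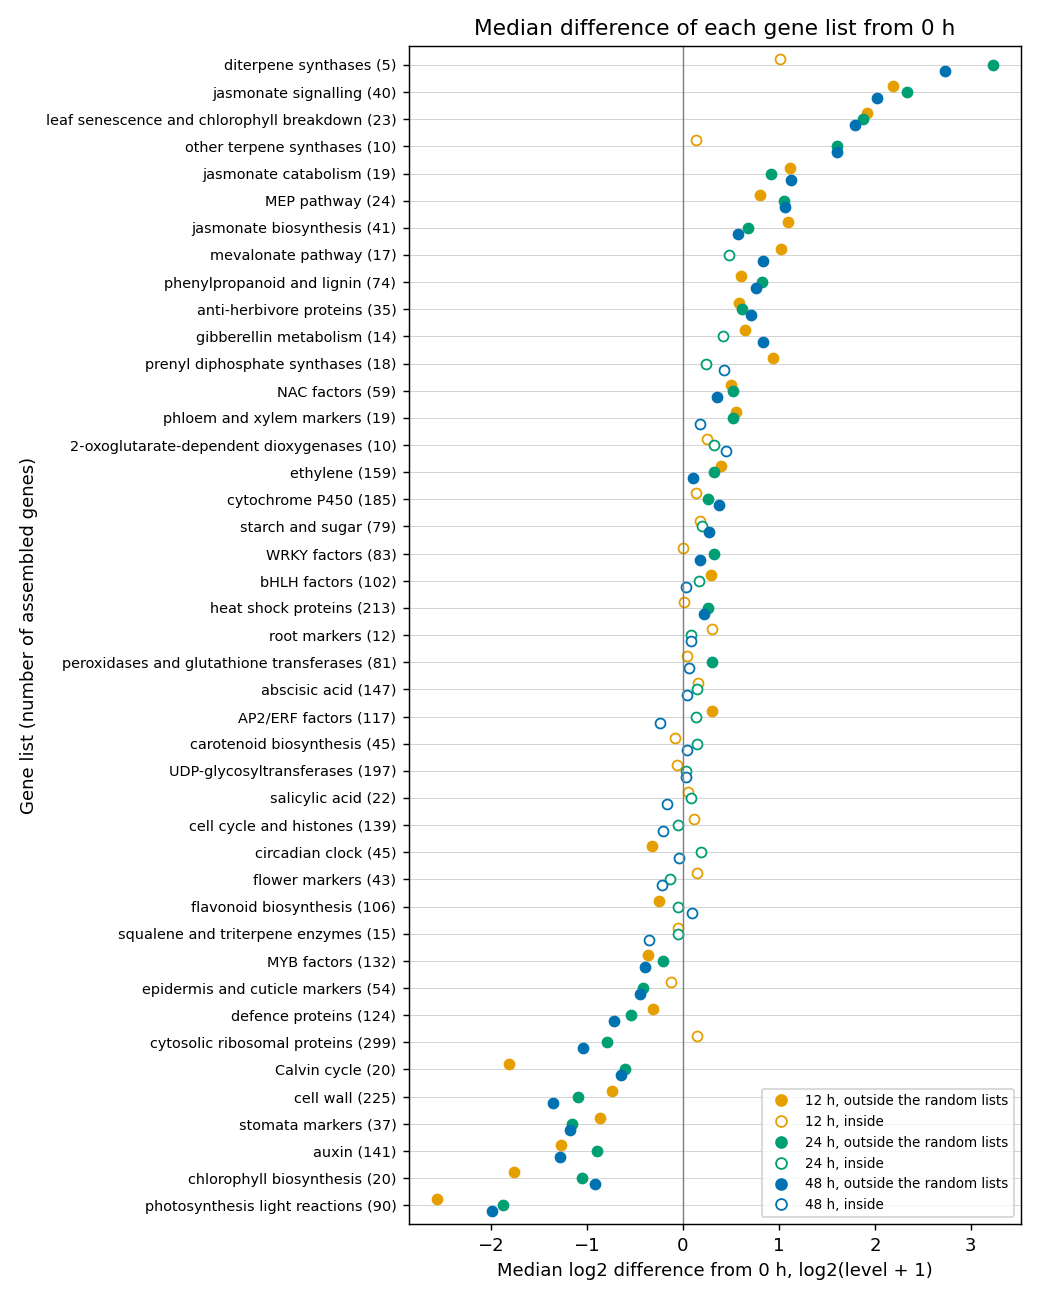
Median log2 difference of level + 1 from 0 h (horizontal axis) for the 43 gene lists with at least 5 assembled genes (vertical axis, number of genes in brackets), at 12 h (orange), 24 h (green) and 48 h (blue). Filled points lie outside the central 95% of 10000 random lists matched on level and open points inside, with light reaction genes between -2.56 and -1.87 and jasmonate signalling genes between 2.02 and 2.34.

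At 48 h the prenyl diphosphate synthase, squalene and triterpene, UDP-glycosyltransferase, dioxygenase, flavonoid, carotenoid, clock, peroxidase, abscisic acid, salicylic acid, bHLH, AP2/ERF, cell cycle, phloem and xylem, flower and root lists lay inside the random lists. The Calvin cycle call was lost with the 10 highest genes left out, at percentile 2.88, with a pseudocount of 0.1, at 3.14, with a level of at least 10, at 6.59, and with 1 assembled gene per Swiss-Prot entry, at 2.71. With 1 assembled gene per Swiss-Prot entry the defence, MYB, NAC, WRKY and epidermis calls were also lost, at medians of -0.22, -0.07, 0.37, 0.19 and -0.04, and the ethylene call was lost with no filter on low values (median 0.03, percentile 94.5) and with pieces summed (median 0). The gibberellin call was lost with a level of at least 10, where 7 members were left at a median of 0.92 and percentile 97.4. The epidermis call was also lost with no filter on low values, at percentile 4.03, and the epidermis and MYB calls with a level of at least 10, at 26.3 and 53.3. Called in other settings alone were, above, flavonoid (0.79), peroxidase (0.49) and bHLH (0.36) lists with a level of at least 10, dioxygenases with pieces summed (0.84) and UDP-glycosyltransferases with median-of-ratios scaling (0.11), and, below, AP2/ERF (-0.35) and cell cycle (-0.28) lists with pieces summed. The lists of plastid-encoded and mitochondrion-encoded genes had 4 and 3 members, too few for a call. Their medians at 12, 24 and 48 h were -0.99, -0.73 and -0.62 for the plastid and 0.51, 0.20 and 0.40 for the mitochondrion.

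Between 12 h and 24 h the 3 largest positive differences were those of genes at low levels at 12 h alone. LHY was at 494 against 0.700, Rubisco activase at 5987 against 31.0, and granule-bound starch synthase (TR14279|c0_g1) at 507 against 1.24, after 321 at 0 h. By 2-fold or more, 3103 genes were higher and 3271 lower at 24 h than at 12 h. Higher genes made up 48.7% of these, against 51.9% with median-of-ratios scaling, 54.3% with a level of at least 10 and 61.5% with the 4-fold rule. The 3 largest negative differences were a CYP72A219 hit (TR79615|c17_g2), at 1291 at 12 h and listed at 0 at 24 h, an epoxide hydrolase hit (TR35027|c1_g3), at 351 and 2.11, and an isoflavone reductase-like gene (TR13440|c4_g1), at 95.6 and listed at 0. With the pieces of its component summed, the isoflavone reductase-like gene was higher by 0.85 at 24 h, and the more abundant piece TR13440|c4_g3 was at 1424 and 2739. On the component of the CYP72A219 hit, the ethylene receptor hit TR79615|c17_g1 was at 4660 at 12 h and 3982 at 24 h. These hits have different names, so summing did not join them.

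Between 24 h and 48 h the 3 largest positive differences were a GDSL lipase (TR18197|c1_g1), at 204 against 16.2, a lipid transfer protein (TR83299|c5_g1), at 430.3 against 38.5, and the isoflavone reductase-like TR13440|c4_g1, at 51.7 against a listed 0. The 3 largest negative differences were a 2-oxoglutarate-dependent dioxygenase of the AOP1 type (TR18171|c0_g1), at 3.11 against 67.8, a beta-amylase (TR18883|c0_g1) at 16.6 and an isoaspartyl peptidase (TR44341|c3_g1) at 31.6 at 24 h, the last 2 listed at 0 at 48 h. For the isoflavone reductase-like gene and the isoaspartyl peptidase the direction turned with pieces summed, to -0.47 and 0.55, and the beta-amylase difference was -0.14. By 2-fold or more, 694 genes were higher and 1324 lower at 48 h than at 24 h. The median difference over all 29399 genes was -0.10, and it was 0 with median-of-ratios scaling. Higher genes made up 34.4% of those counted, against 45.4% with that scaling and 43.4% with the 10 highest genes left out.

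Over the whole course, 14438 genes, or 49.1%, differed from 0 h by 2-fold or more at 1 or more times, and 269 of them in both directions. The number in both directions was 900 with a pseudocount of 0.1 and 21 with the 4-fold rule. Of the genes higher at 12 h, 1842 were higher at all 3 times and 1763 at 12 h alone, within 2-fold of 0 h at 24 and 48 h. Of the genes lower at 12 h, 2850 were lower at all 3 times and 1455 at 12 h alone. Genes higher at both 24 h and 48 h numbered 2767, and genes lower at both 4257, where independent lists of these sizes would share 479.7 and 975. For 12 h and 24 h the shared numbers were 2337 and 3161, against 590.2 and 881, and for 12 h and 48 h they were 2040 and 3309, against 538 and 1024. With a pseudocount of 0.1 the shared higher genes were 4180 (24 and 48 h), 3640 (12 and 24 h) and 3291 (12 and 48 h), where independent lists would share 969, 1127 and 1035. All of these comparisons use the same 0 h column. Unchanged leaves were also simulated with a shared 0 h column. With an assumed noise of SD 0.2 on the log2 scale they shared on average 0.06 higher and 0.02 lower genes. With SD 0.5 the numbers were 281 and 339.2, from lists of on average 1200 higher and 1199 lower genes. These lists are shorter than those of the data, so the shared numbers cannot be set directly beside the observed ones. The noise of these means is not known and the 0 h column cannot be split. Part of the excess may come from the shared 0 h values, and how much is not known.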

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

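The alternatives other than the pseudocount of 0.1 and no filter on low values were chosen after the data were seen. No paired analysis was possible because the table gives 1 mean per time and carries no replicate numbers. For the same reason these settings, chosen before the data were examined, were not run: DESeq2 size factors and its test, voom, limma per library, the filter on CPM in 6 libraries, the fit of 2 groups alone, a stricter adjusted p, leaving out each replicate and an estimated correlation within lists. Lists by KO numbers alone were not run either. With no filter on low values, median-of-ratios scaling, the 10 highest genes left out or pieces summed, each count of genes and each overlap over both directions stayed within 1.5 times the main value. With a pseudocount of 0.1 the overlaps of higher genes, the count of genes in both directions (900 in place of 269) and these counts moved further: 24 h against 12 h, at 9930 genes in place of 6374, and 48 h against 24 h, at 4761 in place of 2018. A smaller pseudocount enlarges the differences of genes at low levels by construction. The 4-fold rule gave 3560, 2911 and 3117 genes at 12, 24 and 48 h against 0 h, 1604 at 24 h against 12 h, 257 at 48 h against 24 h and 5329 at any time, with overlaps of 1743 (12 and 24 h), 1691 (12 and 48 h) and 2271 (24 and 48 h), since it asks for more. A level of at least 10 gave 5334, 4838, 5041, 3639, 1017 and 7386 genes in the same order, with overlaps of 3279, 3163 and 4054, since 13920 genes in place of 29399 were counted. Of the 78 list calls, 78 were kept with median-of-ratios scaling, 77 with the pseudocount, 77 with the 10 highest genes left out, 74 with no filter, 69 with pieces summed, 63 with a level of at least 10 and 58 with 1 assembled gene per Swiss-Prot entry, and none was called in the opposite direction. Lists inside the random lists were called in 3, 6, 1, 2, 5, 12 and 7 further cases under these settings, in the same order. Among called lists the median turned sign for the clock list at 12 h (0.1075, level of at least 10), the defence list at 24 h (0.1103, 1 gene per entry), the MYB list at 24 h (0.0783, level of at least 10, and 0.1886, 1 gene per entry) and the epidermis list at 24 h (0.3816, 1 gene per entry), each then inside the random lists, and the cause was not tested. Among lists not called, the flower list at 12 h turned from 0.1471 to -0.6876 with a level of at least 10 and was then called lower, and the others that turned sign stayed without a call. Of 260 differences of named genes, 5 turned direction with pieces summed: the DnaJ homolog TR74498|c2_g1 at 24 h (0.3436) and 48 h (0.356), the isoflavone reductase-like TR13440|c4_g1 at 24 h against 12 h (0.8493) and 48 h against 24 h (-0.4685), and the isoaspartyl peptidase TR44341|c3_g1 at 48 h against 24 h (0.5506). Summing adds the levels of the pieces of the component that share the Swiss-Prot entry, by construction. It did not join pieces whose entries are of different species, such as those of FTSH 2 and the flavonoid 3',5'-hydroxylase. For these the setting does not show whether a difference holds over all pieces. Depth is unknown, so no lower limit of detection can be given.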

Other observations

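The 3 counts of assembly pieces, the count after median-of-ratios scaling and the ratios of single jasmonate lists given here were chosen after the result was seen. The other tests were set before their results. The 2-fold rule, and leaving out the 10 highest genes as a setting, were chosen after the data were seen. All genes and families of this paragraph were chosen afterwards, the single genes for their level at 24 h, and no list of phosphate genes was fixed beforehand. A peak at 24 h among them is therefore a matter of choice and says nothing about phosphate genes as a group. The glycerophosphodiester phosphodiesterase GDPD1 (TR61771|c1_g1) was at 12.1, 37.6, 706 and 189 at 0, 12, 24 and 48 h, inorganic pyrophosphatase 2 (TR82349|c3_g1) at 1.36, 4.46, 283 and 39.2, and a pair of phospholipase D p1 hits at 3.59, 2.24, 121 and 22.3 (TR26405|c0_g1) and 3.93, 0.857, 76.6 and 13.9 (TR48310|c0_g2). The phosphate sensors SPX2 (TR33231|c0_g1) and SPX3 (TR18287|c0_g1) were at 309.8 and 103 at 24 h, against 16.8 and 9.77 at 0 h. The phosphate transporter 1-7 (TR71205|c0_g1) was at 0.140 at 0 h and 10.8 at 24 h, and transporter 1-3 (TR38474|c0_g1) was listed at 0 at 0 h and at 14.9 at 24 h. SQD1 (TR40971|c0_g1) and the galactolipid synthase MGDG3 (TR21172|c4_g3), which make lipids without phosphorus, were at 52.2 and 39.6 at 24 h against 24.4 and 8.69. The 9 genes named inorganic phosphate transporter had medians of 0, 1.98 and 0.27 at 12, 24 and 48 h, and 5 were higher and 2 lower at 24 h. Other families had less of a peak: 4 of 6 SPX proteins were higher at 12 h already, with medians of 1.13, 1.81 and 0.88, and the 9 purple acid phosphatases had medians of 0.39, 0.51 and 0.10.

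All genes and families of this paragraph were also chosen afterwards, and were not tested as a group. Threonine dehydratase (TR32416|c5_g3) was at 33.1, 2031, 1434 and 2456 at 0, 12, 24 and 48 h, arginine decarboxylase (TR65833|c1_g2) at 91.3, 494, 539.8 and 537, polyphenol oxidase F (TR81983|c2_g2) at 1.82, 737, 295 and 357, and a patatin-like lipase (TR85657|c0_g1) at 3.62, 971, 1873 and 1414. Geraniol synthase (TR26410|c0_g2) was at 0.241 and 107 at 0 and 48 h, nerolidol synthase (TR24462|c6_g2) at 40.2 and 764 at 0 and 12 h, and a beta-caryophyllene synthase (TR48613|c1_g1) at 0.195, 382, 62.9 and 14.0. The 10 cyclic dof factors had medians of -2.69, 0.11 and -0.08 at 12, 24 and 48 h, with 7 lower and 3 higher at 12 h and none past 2-fold later. The 11 chloroplast fructose-bisphosphate aldolases had medians of -3.56, 0.22 and 0.04, with 8 lower and 1 higher at 12 h and 3 lower and 2 higher at 24 h. Among the latter, TR54001|c1_g2 was at 354, 1.84, 404 and 963 and TR83759|c1_g1 at 753, 2.72, 342 and 774. Cyclic dof factor 2 (TR81228|c0_g1) was at 53.0, 8.71, 69.8 and 66.1. The 9 root phototropism proteins had medians of -3.66, -1.43 and -1.89, with TR57010|c0_g2 at 278, 0.672, 42.3 and 17.8. The evening genes ELF4 (TR49144|c0_g1) and ADO3 (TR72951|c0_g1) were at 100.1 and 28.0 at 12 h, and at or below 1.94 at the other times.

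Many genes differed from 0 h at 12 h and no longer at 24 h. For the clock list the median absolute log2 difference was 0.36 at 24 h and 1.12 at 12 h, a ratio of 0.324 (95% of resamples of the genes 0.173 to 0.477), against 0.975 over all genes, which is consistent with a time-of-day effect on clock genes. A transient jasmonate response stays open, since the ratio for 81 jasmonate biosynthesis and signalling genes was 0.787 (0.523 to 1.31). Taken singly, the ratio was 1.07 (0.706 to 1.71) for signalling, whose median was no lower at 24 h (2.34 against 2.19). For biosynthesis it was 0.618 (-0.515 to 1.27), with medians of 0.68 against 1.10. The intervals overlap and both include 1, so a difference between the 2 lists is not shown. The clock result may not extend to the other genes that differed at 12 h alone, because clock times are not given and time of day and treatment cannot be told apart without untreated leaves at 12 h.

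The count of genes lower at 12 h could come from a few genes taking most of the signal. With the 10 highest genes left out and the columns rescaled, 5125 genes were lower, against 5214 as deposited. The other genes already summed to nearly the same at both times (12 h over 0 h 0.991), so rescaling could hardly change this count. That explanation asks for the other genes to be lower together at 12 h. Their sum was nearly unchanged and the median difference over all genes was 0.063, which argues against it as the cause of 2-fold differences. Median-of-ratios scaling takes out a shift common to all genes. With factors of 1.01 at 0 h and 1.08 at 12 h, it lowers the 12 h levels relative to 0 h. The higher count it gave, 5471, follows from this direction and decides nothing by itself. The positive median of 0.063 argues against a downward shift common to all genes in the deposited values as the cause. Whether the authors' normalisation set this median is not known, and a common shift that it removed cannot be seen here. A biological explanation, such as the treatment itself, was not tested.

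Of the genes with a level of at least 20 at 0 h and listed at 0 at both 24 h and 48 h, 17 in all, 10 had a Swiss-Prot name. Another assembled gene of the same Swiss-Prot entry name, species left out, lay in the same component for 7 of the 10, or 70% (exact binomial 95% bounds 34.8% to 93.3%), against 261 of 1072, or 24.3% (21.8% to 27.0%), of genes that were lower by 2-fold at both times but not listed at 0. Counted by component it was 6 of 9, or 66.7% (29.9% to 92.5%). By the full protein name, which also joins the flavonoid hydroxylase pieces, it was 8 of 10, or 80% (44.4% to 97.48%), against 259 of 1072, or 24.2% (21.6% to 26.8%). Some of these zeros may therefore be a matter of how reads were shared between pieces or copies of a gene, and a loss of single transcripts stays open.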
